A study of Mus musculus with 6 samples.

How the data were processed

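Polyadenylated RNA from flash-frozen, ground whole liver of 35 week old mice was sequenced after TruSeq library preparation, per the labels' protocols. The labels give 2 genotypes, PKM2 KO and WT, with 3 independent mice in each and a mixed C57BL/6J x 129SvJ background. They give no sex, litter, batch or date, and the strandedness of the counting is not given in the sources used here.

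The deposited table holds 1 row per gene and 1 column per liver of expected counts, the estimates of reads per gene that RSEM makes when it divides reads among the transcripts they match. Per the submitters' processing notes the tools were Bowtie 1.0.1 and RSEM 1.2.12 and the genome build was mm9. The gene annotation is not given in the sources used here. Over all 23224 rows, those at 0 included, between 21.2% and 23.8% of the expected counts deposited by the authors per library were not whole numbers (compared exactly, with a tolerance of 0), and the library totals differed, so the values carry no scaling between libraries. Of the 23224 rows, 5593 were 0 in all 6 libraries. In 25 rows the gene name had been turned into a date, as spreadsheets do with some symbols. These rows stayed in the library totals, 18 of them were tested, and none is named. Reads that match near-identical genes, such as the Mettl7a, Saa, Gsta, amylase and trypsin families or pseudogenes, were divided by RSEM, so values of single members of such families are uncertain.

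Expected counts were rounded to whole numbers and analysed in R 4.3.3. Genes with low counts were removed with filterByExpr of edgeR 4.0.16 at its default settings, which left 13058 genes. Libraries were scaled by TMM, whose factors ran from 0.8899 in WT 2 to 1.084 in WT 3. Genotypes were compared with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest) with genotype as the only term, all 6 livers in the fit and Benjamini-Hochberg adjustment at a threshold of 0.05. Fold changes are PKM2 KO over WT, on the log2 scale, with an approximate standard error (SE). This SE is the absolute log2 fold change divided by the square root of the F statistic. It is least reliable for genes nearly off in one genotype. Levels are counts per 1000000 (CPM) with TMM scaling, as mean ± SD over the 3 livers of a genotype. A gene at 0 in a whole group was set against a floor of 3 counts over that group. Such floors cover counting error only.

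A total of 39 gene lists with 895 members, drawn from general knowledge of mouse liver, were fixed before the data were examined, as were the tests and the rule for named genes. Of these, 38 had at least 5 tested members and were tested. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and adjusted over the lists. Camera with a correlation estimated for each list and fry, a rotation test of whether a list moves on balance one way, were run beside it. For each list, the number of members past the threshold is also given adjusted over the list alone.

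The rule for named genes took Pkm, then genes past the threshold with a mean of at least 50 counts per library and no overlap between genotypes, filled to 5 per direction with the smallest p. It took the 2 members with the smallest p of each list past the threshold, the 2 most abundant members of each cell type list described, and the Y-linked genes with Xist. Of the genes this rule takes, 2 are not reported here. Names outside this rule are marked in the text as chosen after their values were seen. Gene order along chromosomes came from the RefSeq genes of GRCm38.p6, a different build from mm9, so no coordinates are given. Of the 13058 tested genes, 12949 (99.2%) matched it by symbol or older symbol.

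Library pairs were compared gene by gene with a chi-square statistic. The most similar pair, PKM2 KO 2 and PKM2 KO 3, had 39.31 per gene, far above sampling noise, so no library was counted as a repeat of another. The pipeline was tested on simulated counts with the library sizes of these livers and their dispersion trend, without further spread particular to a gene. Over 12930 simulated genes, 64.6% of 99 genes planted at a log2 change of 1 and 97% of 99 genes planted at a log2 change of 2 were called, with 9 false calls. Alternatives were other scalings (RLE, upper quartile, library totals), no filter or a stricter filter (at least 1 CPM in at least 3 libraries), DESeq2 1.42.0, limma voom, robust quasi-likelihood, unrounded values, a replicate block, the 20 most abundant genes left out, each liver left out in turn, and other thresholds. After the data were seen, a fit with WT 3 as the only WT liver and a quasi-likelihood fit with adjusted deviances were added. Plots were drawn in Python 3.11.15 with matplotlib 3.10.9.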

Results

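Whole-liver transcriptomes were measured in 35 week old mice that lack the M2 form of the glycolytic enzyme pyruvate kinase (PKM2 KO) and in wild-type mice (WT), with 3 livers per genotype. Library totals were 27727048, 31880716 and 33756104 expected counts in PKM2 KO livers 1 to 3 and 27795400, 36125711 and 34091561 in WT livers 1 to 3. Between 15490 and 16060 genes had a value above 0 in each liver. The 20 most abundant genes took 23.4% to 26% of the counts. Transcripts of Alb, which encodes serum albumin, made up 4.06% of WT 2 and 6.93% to 8.56% of the other libraries. The PKM2 KO livers resembled each other more than the WT livers did. The median within-group SD of log2 CPM was 0.144 in PKM2 KO and 0.227 in WT, and the Pearson correlations across genes were 0.9821 to 0.9879 within PKM2 KO and 0.9605 to 0.9661 within WT. Between genotypes they were 0.9578 to 0.9767. WT 1 and WT 3 each correlated better with every PKM2 KO liver (0.9713 to 0.9767) than with the other WT livers.

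The comparison asks which liver transcripts differ when PKM2 is absent from the germline onward. Pkm, the targeted gene, is listed under its older symbol Pkm2, and its count sums both splice forms, PKM1 and PKM2. It was at 9.65, 6.31 and 6.9 CPM in PKM2 KO livers 1 to 3 and at 15.9, 26.6 and 20.6 CPM in WT livers 1 to 3. All 3 PKM2 KO values lay below all 3 WT values, at 7.621 ± 1.78 against 21.05 ± 5.34 CPM (SD, n = 3 each), a ratio of 2.76 with a log2 fold change of -1.47 (SE 0.232). Its adjusted p over all genes was 0.314 in edgeR's quasi-likelihood test, so the difference did not pass the threshold. It passed with DESeq2 (adjusted p = 7.91e-06) and without WT replicate 1 (adjusted p = 0.0472 in edgeR), and over all alternatives the adjusted p ran from 7.91e-06 to 1.

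Of 13058 genes tested, 2 rose and 1 fell in PKM2 KO liver, each with an adjusted p of 0.000719. The 3 genes were nearly off in one genotype. Mettl7a3, which encodes a methyltransferase-like protein, was at 15.41 ± 1.28 CPM (SD, n = 3) in PKM2 KO and had rounded counts of 0 in all WT livers, so it was at least 498-fold higher against a floor of 3 counts over the WT group (0.0309 CPM). Its close paralog Mettl7a2 was at 19.15 ± 0.794 CPM in PKM2 KO and 0.2031 ± 0.148 CPM in WT (log2 fold change 6.57, SE 0.352, and 7.17 without WT replicate 1). Reads can be divided between these copies. The related gene Mettl7a1, chosen after its values were seen, was at 324 ± 19 CPM in PKM2 KO and 278 ± 30.6 CPM in WT (adjusted p = 0.773). Camk2b, the beta subunit of a calcium/calmodulin-dependent protein kinase, fell 86.8-fold from 17.82 ± 3.93 CPM in WT to 0.1987 ± 0.0891 CPM in PKM2 KO (log2 fold change -6.44, SE 0.315). An unadjusted p under 0.05 was reached by 946 genes, 375 higher and 571 lower, where evenly spread p values would give 653. Other ways to split the same livers into groups of 3 gave 170 to 1194 such genes, so 946 is not beyond what other groupings give. The livers of the genotypes did not overlap for 758 genes higher and 819 genes lower in PKM2 KO, 12.1% of those tested where chance gives 10%. The count of calls depended on single WT livers and on the tool, with 51 genes without WT replicate 1, 51 without WT replicate 3 and 99 with DESeq2, always including these 3.

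**Figure D1:**
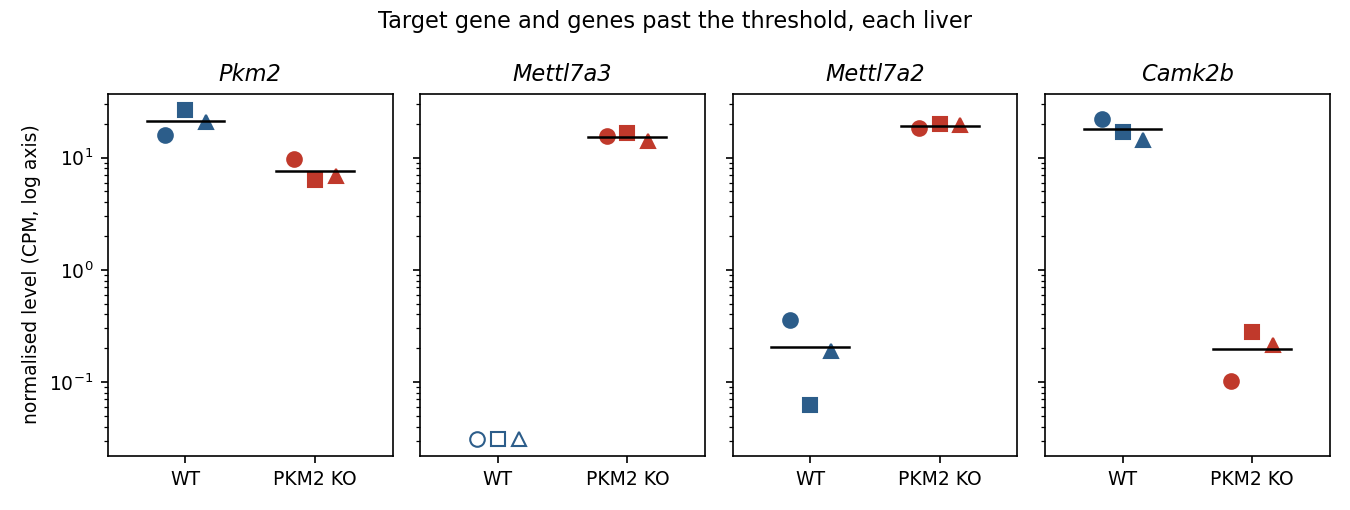
Normalised level in CPM on a log axis of Pkm (listed as Pkm2), Mettl7a3, Mettl7a2 and Camk2b in each WT (blue) and PKM2 KO (red) liver, where circles, squares and triangles are replicates 1, 2 and 3, lines are group means and open symbols at 0.0309 CPM are counts of 0. Pkm lies at 6.31 to 9.65 CPM in PKM2 KO and 15.9 to 26.6 CPM in WT, while the other 3 genes are nearly absent from 1 genotype.

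An adjusted p under 0.1 was reached by 7 genes, the 3 above among them. The genes described next did not pass the threshold and are those with the smallest p among genes with a mean of at least 50 counts, a full gene name and, as the rule for naming requires, no overlap between genotypes. Meg3, a maternally expressed noncoding RNA, was at 23.22 ± 7.21 CPM in PKM2 KO and 6.712 ± 1.09 CPM in WT (log2 fold change 1.79, adjusted p = 0.123). Adamts7, a secreted metalloprotease, had a log2 fold change of 1.42 (adjusted p = 0.122), and Ide, the insulin-degrading enzyme, was at 171.1 ± 29.1 CPM in PKM2 KO and 85.54 ± 11.7 CPM in WT (adjusted p = 0.387). On the lower side, the linker histone gene Hist1h1c had a log2 fold change of -1.20 (adjusted p = 0.115), with 18.6 ± 2.41 CPM in PKM2 KO and 42.8 ± 6.57 CPM in WT. Irak4, a kinase of the interleukin-1 and Toll-like receptor pathways, was at -1.28 (adjusted p = 0.35). The pseudogene Marcksl1-ps4, whose reads can be shared with its parent gene, was at -2.57 (adjusted p = 0.401), with 16, 5.98 and 6.42 CPM in WT livers 1 to 3 and a log2 fold change of -1.96 without WT replicate 1. All 6 of these genes passed the threshold with DESeq2.

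Among hepatocyte programmes, genes of the pericentral zone, the hepatocytes around the central vein, rose together in PKM2 KO liver. All 19 tested members had a positive fold change (mean log2 0.481, camera adjusted p = 4.05e-09, but adjusted p = 0.339 with an estimated correlation), and 7 had no overlap between genotypes. No member passed over all genes or adjusted over the list alone. Camera with the preset correlation gave the list an unadjusted p of 1.07e-10 in the real split. In another split, PKM2 KO 1, WT 2 and WT 3 against the other livers, camera gave 2.31e-06. Of the 19 members, 5 are in another list. Cyp1a2, a cytochrome P450 of drug metabolism, was at 854.8 ± 210 CPM in PKM2 KO and 467 ± 109 CPM in WT (log2 fold change 0.87, SE 0.242, adjusted p = 0.566). It is also in the xenobiotic list and is among the 200 tested genes nearest to Pkm. Lect2, a secreted protein of pericentral hepatocytes, was at 146.9 ± 9.13 and 78.87 ± 23.8 CPM (log2 fold change 0.90, SE 0.216, adjusted p = 0.566). Genes of the periportal zone did not pass, with 9 of 19 positive and a mean of -0.0799 (adjusted p = 0.996).

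Cholesterol synthesis genes rose by a small amount, with 18 of 24 positive and a mean log2 fold change of 0.18 (camera adjusted p = 0.0019, but adjusted p = 0.592 with an estimated correlation). Insig1, a feedback regulator of sterol synthesis, was at 392.1 ± 63.4 CPM in PKM2 KO and 226.3 ± 48.5 CPM in WT (log2 fold change 0.79, adjusted p = 0.566). WT 2 (0.175 relative to the WT mean) lay above PKM2 KO 2 (0.154) on this list. Without WT replicate 2 the mean of the list was 0.275. Xenobiotic metabolism genes were called higher at the preset correlation (31 of 41 positive, mean 0.312, adjusted p = 0.00249, and adjusted p = 0.862 with an estimated correlation). However, Gsta1, a glutathione transferase with close paralogs and the smallest p of the list, was at -1.55. This list lost its call without WT replicate 2 (mean 0.321, adjusted p = 0.0782) or WT replicate 3 (mean 0.242, adjusted p = 0.0798). WT 1 lay above all PKM2 KO livers, and the mean was 0.742 without it and 0.11 without PKM2 KO replicate 1. Bile acid genes rose (14 of 19 positive, mean 0.237, adjusted p = 0.00531, and adjusted p = 0.592 with an estimated correlation). Within it, Hsd3b7, an enzyme of bile acid synthesis, was at 0.51 and Nr0b2, the repressor SHP, at 1.26 (adjusted p 0.583 and 0.594). Without WT replicate 3 the list lost its call (mean 0.182, adjusted p = 0.0848), and without WT replicate 1 its mean was 0.375. Without a filter on low counts the mean was -0.0435, while camera still placed the list higher (adjusted p = 0.014). Genes induced by p53 rose (16 of 20 positive, mean 0.139, adjusted p = 0.022, and adjusted p = 0.339 with an estimated correlation), although Btg2, an antiproliferative gene with the smallest p, was at -0.88, and Bbc3, which promotes apoptosis, was at 0.51. That call was lost without PKM2 KO replicate 2 (mean 0.109), WT replicate 1 (0.135) or WT replicate 2 (0.112), and without WT replicate 3 the mean was 0.218. Its adjusted p was 0.13 without WT replicate 2. Every p53 member overlapped between genotypes. On this list WT 3 (0.0994 relative to the WT mean) lay above PKM2 KO 3 (0.0812). No member of these 4 lists passed over all genes or adjusted over the list alone. Of the tested members, 8 of 41 xenobiotic, 4 of 19 bile acid and 2 of 20 p53 genes are in another list. With WT 3 as the only WT liver the means were 0.851 for the pericentral, 0.279 for the cholesterol and 1.16 for the xenobiotic list. They were 0.43 for the bile acid and 0.0917 for the p53 list. A single WT liver holds no spread between WT mice, so that fit gives no test of these lists.

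Markers of 3 of the 4 immune cell lists fell in PKM2 KO liver, and those of B and plasma cells did not pass (mean -0.147, adjusted p = 0.308). No immune list passed with an estimated correlation. Macrophage and Kupffer cell markers fell, with 22 of 23 tested members negative and a mean log2 fold change of -0.59 (camera adjusted p = 2.1e-07, but adjusted p = 0.339 with an estimated correlation). C1qa, a complement component made by Kupffer cells, was at 27.77 ± 3.01 CPM in PKM2 KO and 41.91 ± 0.774 CPM in WT (log2 fold change -0.59, SE 0.111, adjusted p = 0.466) and was the 1 member that passed adjusted over the list alone. Itgam, the integrin CD11b, was at 1.173 ± 0.328 and 3.324 ± 1.69 CPM. The most abundant members were Mpeg1, at 75.58 ± 9.54 CPM in PKM2 KO and 108.9 ± 40.4 CPM in WT, and the Kupffer cell gene Cd5l, at 77.72 ± 4.05 and 80.21 ± 6.17 CPM. Markers of T and NK cells fell (12 of 15 negative, mean -0.56, adjusted p = 2.46e-05, and adjusted p = 0.339 with an estimated correlation), and 3 passed adjusted over the list alone. Lck, a T cell receptor kinase, was at 0.542 ± 0.0713 CPM in PKM2 KO and 1.163 ± 0.143 CPM in WT. The granzyme gene Gzma was at 0.08537 ± 0.0479 and 0.3637 ± 0.0693 CPM. The most abundant members, Zap70 and Il2rb, were at log2 fold changes of 0.01 and -0.41. The mean of this list was -0.352 without PKM2 KO replicate 2, -0.346 without PKM2 KO replicate 3 and -0.357 without WT replicate 3. Neutrophil markers fell (7 of 7 negative, mean -1.27, adjusted p = 0.000127, and adjusted p = 0.339 with an estimated correlation), with 4 adjusted over the list alone. Mmp9, a matrix metalloprotease, was at -1.62, and the receptor genes Fpr1 and Csf3r were at -0.68 and -0.72. Without WT replicate 2 the neutrophil mean was -0.802. WT 1 and WT 2 also held pancreatic enzyme transcripts, and with WT 3 as the only WT liver the means of the macrophage, T and NK cell and neutrophil lists were -0.706, -0.419 and -1.06.

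Inflammatory cytokine and NF-kB target genes fell as well (20 of 21 negative, mean -0.56, adjusted p = 1.73e-05, and adjusted p = 0.417 with an estimated correlation). Il1rn, the interleukin-1 receptor antagonist, was at 2.069 ± 0.433 CPM in PKM2 KO and 5.384 ± 1.97 CPM in WT (log2 fold change -1.38, SE 0.297) and was the 1 member that passed adjusted over the list alone. The chemokine gene Cxcl1 was at 3.97, 39.3 and 4.39 CPM in WT livers 1 to 3 and at 2.33 to 3.21 CPM in PKM2 KO livers. Acute phase genes were called lower at the preset correlation (22 of 23 negative, mean -1.01, adjusted p = 0.00225, and adjusted p = 0.862 with an estimated correlation). WT 2 set the size of this difference. The serum amyloid gene Saa1 was at 25.7, 2320 and 356 CPM in WT livers 1 to 3 and at 36.4, 27.5 and 54.2 CPM in PKM2 KO livers. Its close paralog Saa2 was at 13.2, 2120 and 204 CPM in WT livers and 10.2 to 26.3 CPM in PKM2 KO livers. WT 1 (-0.883 relative to the WT mean) lay below all PKM2 KO livers (-0.834 to -0.311) on this list. Every acute phase member overlapped between genotypes, and none passed adjusted over the list alone. Without WT replicate 2 the acute phase mean was -0.273 (adjusted p = 0.703), with limma voom it was -0.633, and with WT 3 as the only WT liver it was -0.412. Interferon response genes were called lower at the preset correlation (26 of 30 negative, mean -0.306, adjusted p = 0.0198, and adjusted p = 0.862 with an estimated correlation). Zbp1, a nucleic acid sensor, was at -1.13 and Bst2, the antiviral protein tetherin, at -0.24. Of the 30 members, 1 had no overlap between genotypes, and none passed adjusted over the list alone. WT 1 (-0.531 relative to the WT mean) lay below all PKM2 KO livers (-0.504 to 0.0705). That call was lost without PKM2 KO replicate 2 (mean -0.269), PKM2 KO replicate 3 (-0.18), WT replicate 2 (-0.235) or WT replicate 3 (-0.0987), at adjusted p values up to 0.885. The mean was -0.482 without PKM2 KO replicate 1, -0.512 without WT replicate 1 and -0.584 with WT 3 as the only WT liver.

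**Figure D2:**
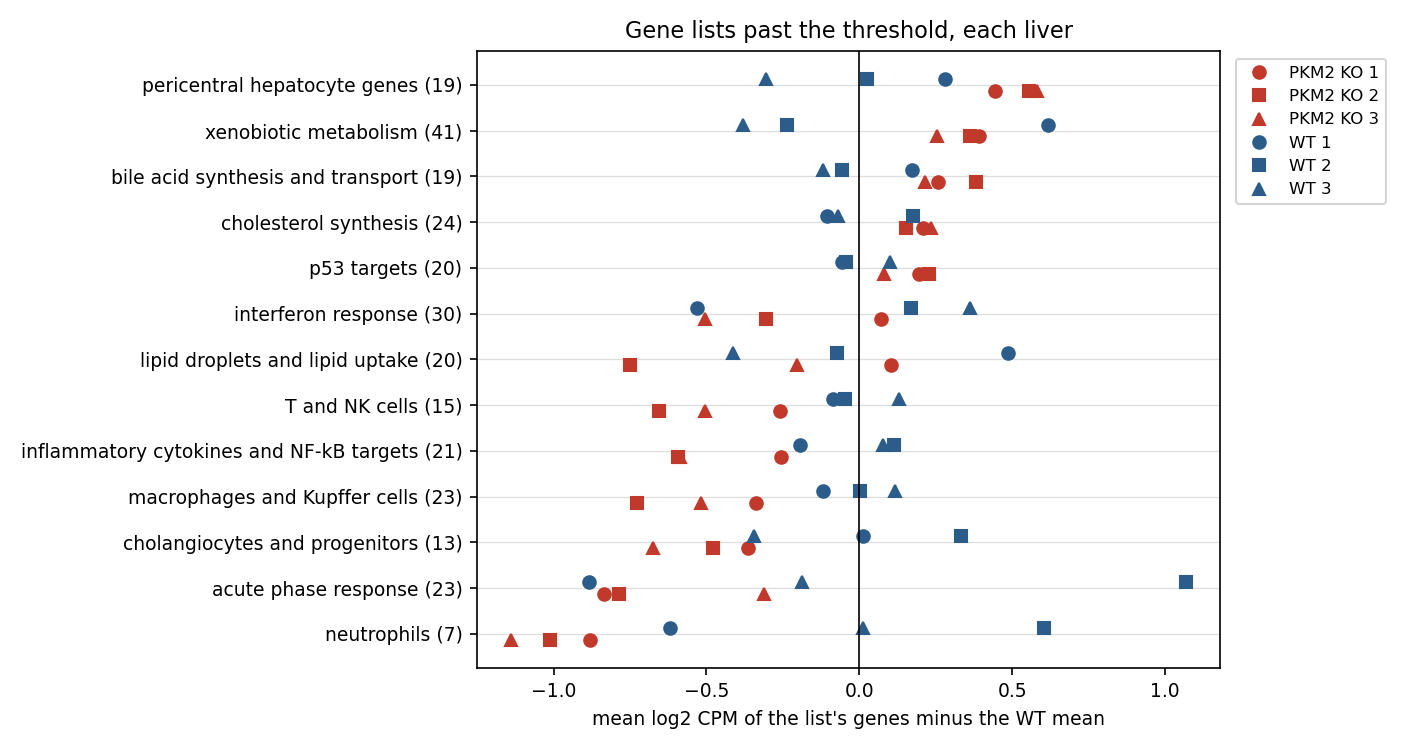
Mean log2 CPM of each gene list past the camera threshold in each liver, relative to the WT mean, with the number of tested genes in brackets; WT livers are blue, PKM2 KO livers red, and circles, squares and triangles are replicates 1, 2 and 3. The PKM2 KO livers lie at -0.728 to -0.339 for macrophage markers and at 0.445 to 0.583 for pericentral genes, apart from the WT livers, while the acute phase value of WT 2 is 1.07. The pancreatic list is left out because of its range.

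Lipid droplet and lipid uptake genes fell (14 of 20 negative, mean -0.359, adjusted p = 0.0102, and adjusted p = 0.714 with an estimated correlation). The fatty acid binding protein genes Fabp4, at 6.259 ± 1.28 CPM in PKM2 KO and 11.48 ± 0.951 CPM in WT, and Fabp5, at 8.365 ± 3.35 and 28.9 ± 15 CPM, were the 2 members that passed adjusted over the list alone. Of the 20 tested members, 4 are in another list, and Fabp4 is also an adipocyte marker. Adipocyte markers had 7 of 7 negative fold changes (mean -0.73, adjusted p = 0.108), at 0.538, 0.964 and -1.5 relative to the WT mean in WT livers 1 to 3 and 0.635, -1.17 and -0.886 in PKM2 KO livers 1 to 3. Without WT replicate 1 the mean of the list was -0.00264 (adjusted p = 0.372), and the call was also lost without PKM2 KO replicate 2 (mean -0.355). The mean was -0.605, -0.61 and -0.674 without PKM2 KO replicate 1, WT replicate 2 and WT replicate 3, and 0.298 with WT 3 as the only WT liver. Markers of cholangiocytes, the bile duct cells, and of liver progenitors fell (11 of 13 negative, mean -0.698, adjusted p = 0.0181, and adjusted p = 0.592 with an estimated correlation), with 1 higher and 2 lower members adjusted over the list alone. Krt19, a keratin of duct cells, was at 3.47, 5.08 and 1.14 CPM in WT livers and 0.724 to 1.12 CPM in PKM2 KO livers, and Cd24a was at -0.83. The abundant member Spp1, a secreted phosphoprotein, was at -0.11. This call was lost without WT replicate 1 (mean -0.688, adjusted p = 0.0505), PKM2 KO replicate 3 (mean -0.713, adjusted p = 0.0778) or WT replicate 2 (mean -0.374, adjusted p = 0.0656), and the mean moved by over 1.5 times only in the last of these. WT 1 and WT 2, the livers with the highest means, held pancreatic transcripts, and with WT 3 as the only WT liver the mean was -0.125. The call was also lost with the stricter filter (mean -0.505, adjusted p = 0.165).

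Pancreatic enzyme transcripts were high in 2 of the 6 livers. Amy2a5, a pancreatic amylase gene, was at 1520 CPM in WT 1, 4310 CPM in WT 2, 9.91 CPM in WT 3 and 7.2 to 15.1 CPM in the PKM2 KO livers. Ctrb1, which encodes chymotrypsinogen, was at 319, 814 and 3.09 CPM in WT livers 1 to 3 and 1.41 to 3.39 CPM in PKM2 KO livers, and Try4, a trypsinogen gene, followed the same order. All 15 acinar markers had negative fold changes (mean -6.97, camera adjusted p = 5.27e-09, but adjusted p = 0.592 with an estimated correlation). None passed over all genes, and 15 passed adjusted over the list alone. With WT 3 as the only WT liver the mean was 0.203. Acinar transcripts made up 0.348% of the counts of WT 1, 0.888% of WT 2 and 0.00374% of WT 3, against 0.00371% to 0.00647% in PKM2 KO.

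**Figure D3:**
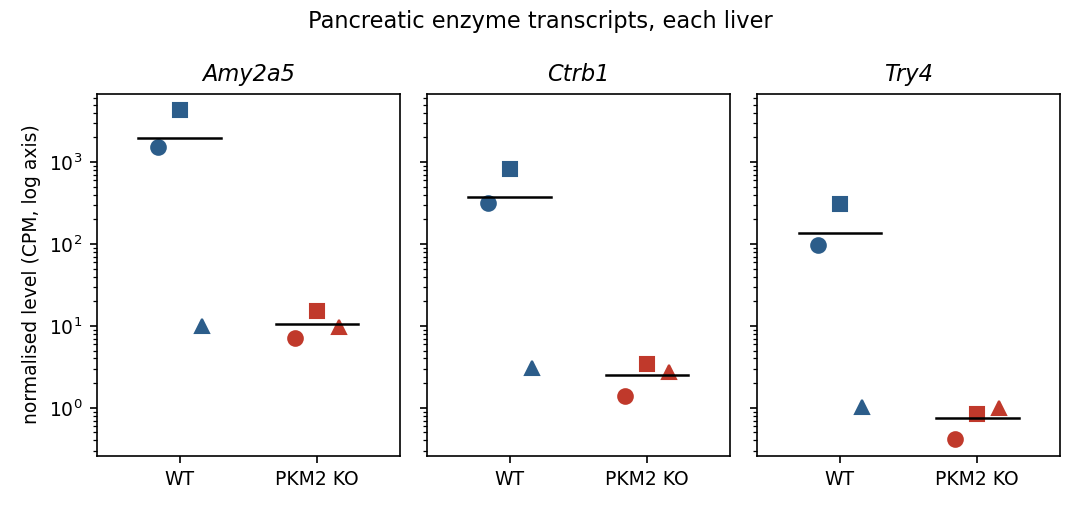
Normalised level in CPM on a log axis of the pancreatic genes Amy2a5, Ctrb1 and Try4 in each WT (blue) and PKM2 KO (red) liver, where circles, squares and triangles are replicates 1, 2 and 3 and lines are group means. WT 1 and WT 2 stand at 1520 and 4310 CPM for Amy2a5, while WT 3 (9.91 CPM) lies within the range of the PKM2 KO livers.

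The other 24 lists did not pass (camera adjusted p 0.108 to 0.996). Among metabolic lists, glycolysis had 8 of 27 genes positive and a mean of -0.125 (adjusted p = 0.349), and Pkm itself was the 1 member past the threshold adjusted over the list alone. Fatty acid synthesis had a mean of 0.118 (adjusted p = 0.126). Its regulator Srebf1, chosen after its values were seen, was at 454.8 ± 79.9 CPM in PKM2 KO and 243.6 ± 30.8 CPM in WT (log2 fold change 0.90, adjusted p = 0.488 over all genes) and passed adjusted over the list alone. The means were 0.0778 for gluconeogenesis and glycogen (adjusted p = 0.232), -0.00992 for oxidative phosphorylation (0.962), -0.1 for fatty acid oxidation and PPARalpha targets (0.533) and -0.135 for serine and one-carbon metabolism (0.803). They were -0.434 for the integrated stress and unfolded protein responses (0.166), 0.0329 for NRF2 targets (0.304), -0.185 for hypoxia genes (0.962), -0.182 for insulin and growth hormone signalling (0.863) and -0.129 for regulators of Pkm splicing (0.971). Proliferation genes had a mean of 0.0876 (20 of 36 positive, adjusted p = 0.166). Liver tumour and fetal liver genes had a mean of -0.398 (12 of 17 negative, adjusted p = 0.308), and Meg3, with its positive fold change, was the 1 member past the threshold adjusted over the list alone.

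Markers of several other cell types did not pass either. Hepatocyte markers had a mean of 0.0641 (17 of 24 positive, adjusted p = 0.19), with the abundant Alb at 79430 ± 4830 CPM in PKM2 KO and 64050 ± 16500 CPM in WT and Trf, which encodes transferrin, at 14940 ± 421 and 15100 ± 1950 CPM. Liver endothelial markers had a mean of -0.0104 (8 of 17 positive, adjusted p = 0.616), with Eng and Ehd3 at log2 fold changes of 0.08 and 0.12. Stellate cell and fibrosis genes had a mean of -0.0814 (14 of 27 positive, adjusted p = 0.782), with Dcn and Reln at 0.15 and 0.45. Red blood cells (mean 0.168, adjusted p = 0.314) and skeletal muscle (0.987, 0.319) did not pass, nor did circadian clock genes (0.0616, 0.244). For 6 lists the mean, the median and the camera direction did not share a sign, namely fatty acid oxidation, endothelial cells, stellate cells, serine metabolism, oxidative phosphorylation and female-biased genes.

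All 6 livers carried transcripts of male mice. Xist, the noncoding RNA of the inactive X chromosome, had 0 to 5 counts per liver. The Y-linked genes were expressed in PKM2 KO and WT livers, with Ddx3y at 72.18 ± 3.61 and 69.12 ± 12.1 CPM, Eif2s3y at 42.53 ± 2.21 and 35.45 ± 3.88 CPM, Kdm5d at 13.81 ± 1.04 and 11.07 ± 4.4 CPM, and Uty at 12.73 ± 1.18 and 13.97 ± 2.29 CPM. Liver genes with male-biased expression had a mean log2 fold change of -0.743 (10 of 25 positive, adjusted p = 0.847), and those with female-biased expression 0.134 (8 of 17 positive, adjusted p = 0.996).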

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

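The fit with WT 3 as the only WT liver, in which that liver is assumed to vary like the PKM2 KO livers, and the fit with adjusted deviances were chosen after the data were seen; all other alternatives were planned. The 3 genes past the threshold (Mettl7a3, Mettl7a2 and Camk2b) were shared by every alternative run. With 2 higher and 1 lower in the reported fit, the counts moved with the test and the livers used, and the cause was not tested except where stated. Genes higher and lower numbered 26 and 73 with DESeq2 (14 of the 99 from the acinar list), 4 and 2 with the robust fit, 4 and 3 with the replicate block, 4 and 3 at an adjusted p under 0.1, and 90 and 73 with WT 3 alone. Lower genes numbered 2 with library totals alone, without a filter (which tests 17606 genes), with limma voom and with adjusted deviances. Leaving out each liver in turn gave 2 to 27 higher and 1 to 42 lower genes. Without WT replicate 1 there were 27 higher and 24 lower, and without WT replicate 3 there were 9 and 42, 15 of these 51 from the acinar list. The Pkm fold change kept its direction (log2 -1.664 to -1.262 with a liver left out) and crossed the threshold with DESeq2 (-1.461) and without WT replicate 1.

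Gene lists passing numbered 5 higher and 9 lower with the preset correlation, 0 and 0 with an estimated correlation, and 0 and 0 with fry. At an unadjusted p under 0.05, 5 lists passed with the estimated correlation and 6 with fry. With WT 3 alone 8 lists were higher, and leaving out each liver gave 3 to 10 higher and 6 to 12 lower. The pericentral, cholesterol, macrophage, inflammatory, T and NK cell and neutrophil lists passed with the preset correlation under every other alternative that gave a value for them. The fit with WT 3 alone is left aside here. The stricter filter left fewer than 5 T and NK cell and neutrophil members, so these 2 lists were not tested there. Of their members, 2 of 15 and 4 of 7 were above 1 CPM in all PKM2 KO livers, so both lists rest largely on low counts. The acinar mean turned to 0.203 and the lipid droplet mean to 0.298 with WT 3 alone, and the bile acid mean to -0.0435 without a filter on low counts, where camera kept it higher. The cause of the last 2 was not tested.

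Replicate numbers gave no sign of pairing the livers. Once each gene's group mean was subtracted, same-numbered PKM2 KO and WT livers had correlations of -0.0509, 0.0266 and -0.0915 across genes. The block gave 7 genes in place of 3, 6 higher and 10 lower lists and an acute phase mean of -0.638, and livers did not all correlate best with their own number.

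Of 1079 values of named genes under alternatives, 1021 kept direction and side of the threshold, 43 newly passed and 15 changed direction. The changes of direction were in genes below the threshold. With a liver left out, log2 fold changes spanned -0.1343 to 0.1532 for Zap70, -0.09416 to 0.09041 for Trf, -0.06936 to 0.1503 for Ddx3y, -0.01147 to 0.1479 for Eng and -0.1964 to 0.01821 for Spp1. Trf was at 0.004102 with library totals alone. With WT 3 alone the values were 0.09227 for Cd5l, -0.03907 for Dcn, -0.0247 for Eng, -0.05036 for Ddx3y, 0.1069 for Amy2a5 and -0.1762 for Kdm5d. Simulated livers of these depths gave calls for 64.6% of genes with a log2 change of 1 and 97% with a change of 2. They carried only the dispersion trend, so they cannot say which real changes were missed. In the reported fit larger differences were also not called, with Pkm at -1.47 and the 15 acinar genes at a mean of -6.97.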

Other observations

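The tests on pancreatic tissue, genotype alone, the share of other cells, linkage and the Mettl7a copies were chosen after the results they bear on were seen. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, the noncoding RNA Rian, the insulin genes and the neighbours of Pkm named here were also chosen after their values were seen. Mt1 was at 23.5, 488 and 304 CPM in WT livers 1 to 3 and 12.5 to 15.4 CPM in the PKM2 KO livers (log2 fold change -4.27, SE 0.937, edgeR adjusted p = 0.523), and Mt2 was at 5.51, 124 and 65.2 CPM against 2.86 to 4.1 CPM. Both passed with DESeq2 and without WT replicate 1. Rian, which lies in the same imprinted gene cluster as Meg3, was at 15.51 ± 2.18 CPM in PKM2 KO and 5.736 ± 2.22 CPM in WT (log2 fold change 1.44, SE 0.295, adjusted p = 0.496), the same direction as Meg3.

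Genes next to Pkm in the gene order of GRCm38 had small p values more often than other genes. Of the 200 tested genes nearest to Pkm, 100 on each side on chromosome 9, 13 (6.5%) had an unadjusted p under 0.01, against 207 of 12748 others (1.62%; Fisher's exact test across genes, which are not independent, two-sided p = 3.72e-05). The other splits of the livers gave 0 to 5 such neighbours, and the smallest adjusted p among the neighbours was 0.488. They included the cytochrome P450 genes Cyp1a2 and Cyp1a1, the cytokine gene Il18 and Nnmt. The window and the p limit were set once, without trying others.

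There are 10 ways to split the 6 livers into groups of 3, too few for a share under 0.05. The real split gave 3 genes past the threshold, and the highest other split gave 1; 1 of the 10 splits, the real one, reached 3. For gene lists the real split gave 14 and the highest other split 20, and 6 of the 10 splits reached 14. Different sexes in the groups are argued against by Xist, at most 0.152 CPM in any liver, while the lowest level of a Y-linked gene was 6.86 CPM.

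Pancreatic enzyme transcripts stood out in WT 1 and WT 2. Genotype alone would give the WT livers a shared level, but the median range among them over the 15 acinar genes was 8.25 on the log2 scale, against 1.06 among PKM2 KO livers. A candidate explanation is pancreatic tissue taken along with the liver. The insulin genes Ins1 and Ins2, which acinar cells do not express, had 16 counts together in WT 1 and 317 in WT 2 and 0 in the other 4 libraries, and the 15 acinar genes were 3-fold higher in WT 2 than in WT 1 with an SD of 0.202 on the log2 scale. Of these 15 genes, 5 were above 1 CPM in all PKM2 KO livers.

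The macrophage, T and NK cell and neutrophil lists were lower in PKM2 KO liver with the preset correlation, but not with an estimated correlation (adjusted p = 0.339 each), and B and plasma cell markers did not pass. Endothelial markers gave no sign of a lower share of all cells other than hepatocytes. Their mean log2 fold change was -0.0104 (95% interval over members -0.142 to 0.121), against a macrophage mean of -0.59. That interval covers the spread between genes of the same livers, not between mice. Relative to the WT mean, the endothelial list lay at -0.00671 to 0.0289 in PKM2 KO livers and -0.181 to 0.094 in WT livers. Pancreatic tissue in WT 1 and WT 2 stays open as a part of the difference: macrophage markers in WT 2 differed from the level that WT 1 and the acinar ratio predict by a mean log2 ratio of -0.231 (95% interval -1.09 to 0.632), while in WT 3, a single liver without the pancreatic signal, 17 of 23 markers lay above all PKM2 KO livers. The macrophage list had a smaller p in the real split (1.66e-08) than in the other splits (smallest 8.68e-05), which held for 1 of 10 splits. Fewer immune cells or less expression per cell may underlie the lower lists, and whole tissue does not separate them. An effect of genotype stays open.

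Camk2b, Mettl7a2 and Mettl7a3 were on in one genotype and nearly off in the other. Linkage to the targeted gene is argued against, since 0 of the 3 lie on chromosome 9 with Pkm (Camk2b is on chromosome 11 and the Mettl7a genes are on chromosome 15). For the Mettl7a genes, a shift of reads between copies at an unchanged total would need a log2 fold change of -0.19 in Mettl7a1. The value was 0.223 (SE 0.133). The total of Mettl7a1, Mettl7a2 and Mettl7a3 was 359 CPM in PKM2 KO and 278 CPM in WT. A shift of reads beside a change in that total therefore stays open. Segments of C57BL/6J or 129SvJ origin that the livers of a genotype happen to share may contribute. Among the 100 leading genes without overlap, 19 pairs lay within 10 genes of each other. Random draws, 10000 in number, gave 7.56 on average and 13 at the upper end of their 95% range. The other splits of the livers gave 7 to 19 such pairs, several of them above 13. The excess over random draws is therefore not particular to genotype, and shared segments cannot be told apart from shared regulation of neighbouring genes. Strain genotypes were not analysed here.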
